A study of Homo sapiens with 4 samples.

How the data were processed

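RNA of PC-3 cells transfected with siRNA2 or siRNA3 was compared with RNA of non-transfected PC-3 cells on 4 two-colour Agilent arrays of design 014850, with 2 arrays for each siRNA and the dyes exchanged between them. Per the labels' protocols, cells were transfected with Interferin in 6 wells for each of 3 siRNAs, RNA was extracted with TRI Reagent, and 50 ng of total RNA was amplified and labelled for each channel. The siRNA not arrayed was not analysed here, and no control siRNA was analysed here. The deposited file names call the control channel "Negative" while the labels call it non-transfected, and the labels were followed. The dye of the transfected RNA was taken from the labels.

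Per the file headers, the arrays were read with Feature Extraction 10.7.1.1 and protocol GE2-v5_95_Feb07, on a design built on hg18. The spot and local background values are median pixel intensity values for each channel, as scanned, per the file headers. The processed signals are intensity values that were background-subtracted, spatially detrended and dye-normalized with linear and lowess factors, per the file headers. The scanner's log ratio is the log10 of Cy5 over Cy3 processed signal, per the file headers. The deposited series table holds the authors' log2 ratios. Their direction and scale were not stated and were read from the data: against the scanner's ratios, turned to transfected over non-transfected, the slopes were 0.946 to 1.137 and the correlations 0.802 to 0.884. How the authors made these log2 ratios is not stated in the deposited records.

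Each array held 45015 spots, 43376 of them not controls, and 154 to 248 spots on an array were marked as outliers. In the channel of the transfected RNA, 74.3%, 53.9%, 74.6% and 56.5% of the non-control spots were well above background on siRNA2 replicates 1 and 2 and siRNA3 replicates 1 and 2, and in the non-transfected channel 59.4%, 73.8%, 62.4% and 71.9%. The files carry no mean signal column, so the median signal was used, also where the plan named the mean signal. Probes were named through their accession and the RefSeq gene table of assembly GRCh38.p14: 26222 of 41000 non-control probes (64.0%) matched 1 symbol, and 14778 were kept under the accession or probe name. The 17721 symbols included 835 of the 850 list members.

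The design, the alternatives, the rule for naming genes and the 21 gene lists were fixed before the data were examined. Median signals were corrected with limma 3.58.1 (normexp, offset 50) and normalized by loess within each array, with control and outlier spots given weight 0. The sign was turned so that each log2 ratio is transfected over non-transfected, and spots of a probe were averaged. Probes well above background in at least 1 channel on at least 2 of 4 arrays were kept, 30241 in all. The probe with the highest mean intensity stood for each of 23088 genes, 14094 of them with a symbol. Of 5430 genes with more than 1 tested probe, 0 had probes that passed the threshold in opposite directions in the mean comparison. Probes that differed without both passing were not counted.

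A linear model with 1 coefficient for each siRNA was fitted with limma, and the log2 ratios of siRNA2, of siRNA3, their mean and their difference (siRNA2 minus siRNA3) were tested against 0 with moderated t statistics (2 residual and 2.89 prior degrees of freedom). P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 counted as passing. The SE is the moderated SE of limma. The genes named are, for siRNA2, siRNA3 and the mean, the 10 largest rises and the 10 largest falls among genes that passed, have a symbol and had the same sign on every array of the comparison. For the difference they are 6 in each direction that passed with arrays that do not overlap, or, with none past the threshold, the 5 in each direction with the smallest p, which are said not to pass. For each list they are the 3 members with the largest moderated t in size in the mean. Other genes, among them further list members given as examples and the genes that passed with both siRNAs, were chosen after their values were seen.

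Gene lists covered interferon-stimulated genes, NF-kB and inflammation, G2/M and mitosis, DNA replication and G1/S, p53 targets, apoptosis, epithelial, mesenchymal, invasion, androgen-responsive luminal, neuroendocrine and leukocyte genes, the unfolded protein response and ATF4, cholesterol, hypoxia, heat shock, RNA interference, histones, ribosomal proteins, oxidative phosphorylation and neighbours of the target on chromosome 10. They were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, and adjusted over the 21 lists in each comparison. With an estimated correlation no list passed in any comparison, also where the estimate lay below the preset value. The estimate was above the preset value for G2/M and mitosis (0.591) and for DNA replication and G1/S (0.453). For cholesterol with siRNA3 the estimate was -0.0271, and the unadjusted p of camera was 8.83e-10 with the preset and 0.019 with the estimate. With an estimated correlation camera takes its p from the 2 residual degrees of freedom. With the preset it uses nearly as many as there are genes. A failure with the estimate can thus reflect these few degrees of freedom, and is not by itself a sign of correlation among the members. Counts adjusted over the list alone used the same p-values of the members, adjusted among the members only. Another 3 lists were written after the values of some members were seen, and only their medians and counts are given, with no test of the list.

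Alternatives were no background correction, an offset of 16, Agilent's processed signals, median centring, Aquantile scaling between arrays, the authors' log2 ratios, 2 other filters, the mean over a gene's probes, a term for dye orientation, an intensity trend with robust prior, 2 other thresholds, each siRNA fitted alone, the siRNA as the replicate, and leaving out each array. The limma fit was tested on simulated data with 200 changed genes of 23088 in 20 simulations. At log2 changes of 0.5, 1 and 2 it recovered 24.9%, 96.7% and 99.9% in the mean, 2.16%, 74.5% and 99.1% with siRNA2, 1.57%, 75.7% and 99.2% with siRNA3, and 0.0746%, 10.7% and 94.2% in the difference, and 7.7% to 9.2% of calls were false. With no change and independent genes, 0.2 of 84 list tests passed per simulation (10 simulations). The work used R 4.3.3, data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.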

Results

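Gene expression was profiled in PC-3 cells, an androgen-independent line from a bone metastasis of prostate cancer, after transfection with small interfering RNAs (siRNAs) against the long non-coding RNA PCAT5. Of 3 siRNAs transfected, 2 were arrayed, siRNA2 and siRNA3. Each was measured on 2 Agilent arrays, and on every array the RNA of transfected cells was hybridised together with the RNA of non-transfected PC-3 cells in the other dye. The transfected RNA carried Cy3 in replicate 1 of each siRNA and Cy5 in replicate 2. All 4 arrays lay on 1 slide and were scanned in 1 session. In the Cy3 channel, 71.9% to 74.6% of the non-control spots were well above background, and in the Cy5 channel 53.9% to 62.4%. Median spot signals ranged from 67 to 137 intensity units over local backgrounds of 30.5 to 49, and no spot was saturated. Log2 ratios of transfected over non-transfected cells correlated across genes at r = 0.541 between the siRNA2 arrays and at r = 0.543 between the siRNA3 arrays, against 0.251 to 0.479 between arrays of different siRNAs; genes are not independent replicates. With Agilent's processed signals the values were 0.588 and 0.554 within siRNAs and 0.364 to 0.595 between them. The SD of the log2 ratios over genes was 0.241 on siRNA2 replicate 1 and 0.421 to 0.528 on the other arrays. Spike-in control RNAs, which are added to the labelling reactions, read 2.82 and 2.96 log2 units higher in the siRNA2 channel than in the non-transfected channel relative to their designed ratios, against 0.21 and 0.26 for siRNA3. Loess centred the log2 ratios of each array near 0 (medians -0.019 to 0.023). Log2 ratios and folds, those of siRNA2 included, are thus relative to the other genes of the array and were not scaled to the spike-in controls. The number of arrays limits the precision of every value. Nothing in the labels says whether the arrays of 1 siRNA came from separate cultures or from the same RNA. The limma p-values of single genes thus measure only the spread between arrays, which may be technical. That spread is taken between arrays of the same siRNA. The SE and p of the mean of both siRNAs thus leave out the spread between the siRNAs. The camera p-values with the preset correlation rest on the spread between genes and do not measure the spread between arrays. The non-transfected RNA was treated as 1 control sample, each ratio was tested against 0, and the control's own spread is left out.

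The targeted transcript itself was not measured here. RefSeq lists the name that the labels give the target as a synonym of PCAT5, a long intergenic non-coding RNA gene on chromosome 10, and 0 of the 41000 non-control probes were named for it, so no check of the knockdown was made. Probes were not matched to the transcript by sequence, and 14778 had no symbol. Among 11 measured neighbours on the short arm of chromosome 10, no gene passed the threshold with either siRNA or in their mean (limma, 11 of 11 with adjusted p of 0.05 or more, 2 lower and 1 higher when adjusted over the list alone in the mean). FZD8, a Wnt receptor gene, had a mean log2 ratio of -0.89 ± 0.21 (SE, n = 4 arrays, adjusted p = 0.0944), with values from -0.20 to -1.50. NRP1, a co-receptor of vascular endothelial growth factor, had 0.41 ± 0.08 (adjusted p = 0.0678), and PARD3, a cell polarity gene, had -0.33 ± 0.08 (adjusted p = 0.0942).

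The first comparison asked which genes differed from non-transfected cells on average over both siRNAs. Of the measured genes, 17 of 49 interferon-stimulated and 11 of 36 NF-kB and inflammatory genes rose and 13 of 54 mitotic genes fell, in lists that did not pass with an estimated correlation (adjusted p = 0.26, 0.37 and 0.37). No list passed that test in any comparison, whatever its estimated correlation, so it does not single out these lists. It rests on 2 residual degrees of freedom. With fry the interferon list passed in the mean (adjusted p = 0.042), while the NF-kB (0.056) and G2/M lists (0.077) did not. RSAD2, which encodes the antiviral enzyme viperin, rose by 2.80 ± 0.08 log2 units (SE, n = 4 arrays, limma adjusted p = 0.0117), a 6.98-fold difference, and its values lay between 2.48 and 3.17. UBD, the cytokine-induced ubiquitin-like modifier FAT10, rose by 3.59 ± 0.31 (adjusted p = 0.0286), with 1.76 on siRNA2 replicate 1 and 3.62 to 4.60 on the other arrays. BIRC5, the mitotic and survival protein survivin, fell by 2.21 ± 0.10 (adjusted p = 0.0134), a 4.62-fold difference. CENPF, a kinetochore protein, fell by 1.95 ± 0.09 (adjusted p = 0.0134).

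With limma, 486 of 23088 genes passed an adjusted p of 0.05 in the mean of both siRNAs, 282 higher and 204 lower, and 472 of them had the same sign on all 4 arrays. The other largest rises were those of RTP4 (3.08), a receptor-transporting protein induced by interferon, COXFA4L3 (2.75), a paralog of a cytochrome c oxidase subunit, and the phospholipase and acyltransferase PLAAT2 (2.59). They were followed by the type III interferon IFNL2 (2.43), the interferon-induced IFIT2 (2.38), the chemokine CCL5 (2.36), the long non-coding RNA UCA1 (2.24) and the mitochondrial superoxide dismutase SOD2 (2.22). Adjusted p for these genes ran from 0.0134 to 0.0465. IFNL2 has near-identical copies, and its probe was not checked against them. The other largest falls were those of the chromatin protein HMGB2 (-2.01), cyclin B1 (CCNB1, -1.84), the mitotic kinase PBK (-1.82), the chaperone HSP90AA1 (-1.75), the mitotic kinesin KIF2C (-1.64), the stress kinase MAP3K20 (-1.62), thymidylate synthase (TYMS, -1.59) and caveolin-1 (CAV1, -1.53). Their adjusted p ran from 0.026 to 0.046. MAP3K20 had -0.66 with siRNA2 (limma adjusted p = 0.509) and -2.58 with siRNA3.

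**Figure D1:**
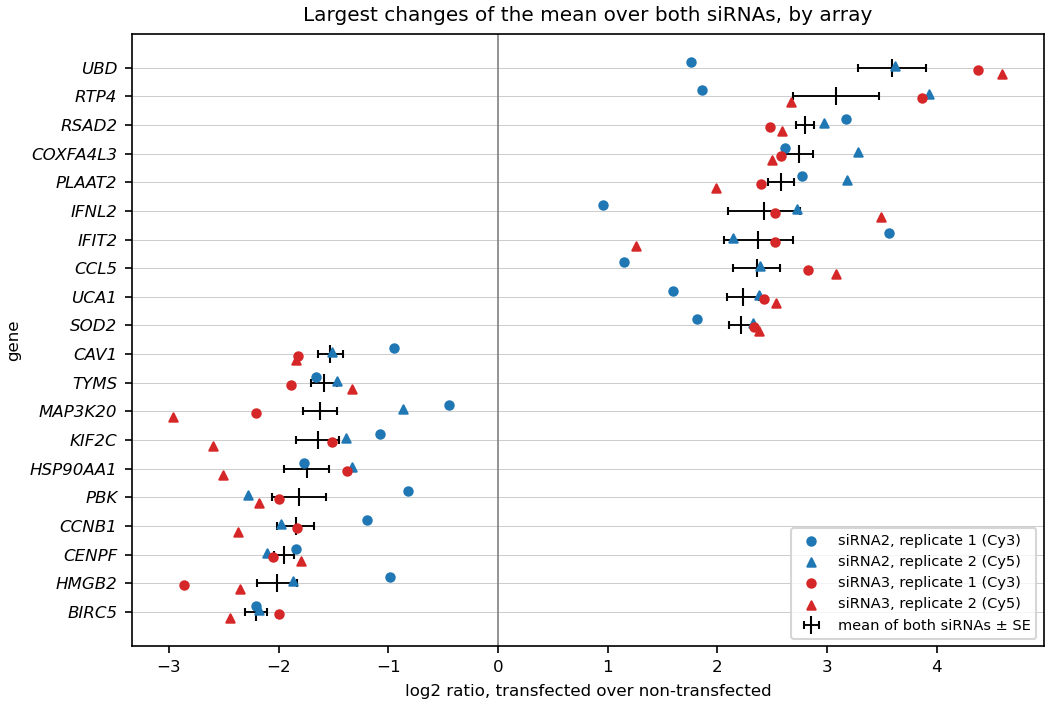
Log2 ratios of transfected over non-transfected PC-3 cells (x axis) for the 10 largest rises and the 10 largest falls in the mean of both siRNAs, with 1 point per array and the limma mean ± SE in black. The naming rule required the same sign on the 4 arrays, and UBD ranged from 1.76 to 4.60.

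Of 49 measured interferon-stimulated genes, 17 rose and none fell in the mean of both siRNAs, while 32 did not pass; adjusted over the list alone, 32 rose and 1 fell. BST2, the virion-tethering protein tetherin, rose by 1.74 ± 0.08 (adjusted p = 0.0134), the protease USP18 by 1.36 ± 0.08 (adjusted p = 0.0196), and OASL by 1.63 ± 0.10 (adjusted p = 0.02). The list's median log2 ratio was 0.83 (limma's camera, adjusted p = 3.53e-18), with adjusted p = 0.26 with an estimated correlation. With median centring the median was 0.27. Of 36 genes of NF-kB signalling and inflammation, 11 rose, none fell and 25 did not pass; adjusted over the list alone, 23 rose and 3 fell. The cytokine IL6 rose by 1.90 ± 0.08 (adjusted p = 0.0134), the apoptosis inhibitor BIRC3 by 1.39 ± 0.09 (adjusted p = 0.02), and NFKBIA, the inhibitor of NF-kB, by 1.57 ± 0.11 (adjusted p = 0.0236). The median of this list was 0.45 (camera, adjusted p = 4.06e-12; adjusted p = 0.37 with an estimated correlation), and over the alternatives it ran from 0.35 to 1.34.

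Of 54 genes of G2/M and mitosis, 13 fell and none rose in the mean, 41 did not pass, and 52 had negative values on all 4 arrays. Adjusted over the list alone, 51 fell. Examples were BUB3 (-0.82 ± 0.07, adjusted p = 0.0286), of the spindle checkpoint, PRC1 (-1.22 ± 0.11, adjusted p = 0.0286), of cytokinesis, and the mitotic kinase AURKA (-1.14 ± 0.13, adjusted p = 0.0368). The median was -0.91 (camera, adjusted p = 1.93e-26; adjusted p = 0.37 with an estimated correlation), and over the alternatives it ran from -1.61 to -0.68. Of 54 genes of DNA replication and G1/S, 4 fell, TYMS, UHRF1, PCNA and TK1, and 50 did not pass; adjusted over the list alone, 40 fell and 1 rose. The replication clamp PCNA fell by 0.92 ± 0.09 (adjusted p = 0.0296). The list's median was -0.60 (camera, adjusted p = 4.96e-16; adjusted p = 0.41 with an estimated correlation), and over the alternatives it ran from -1.12 to -0.43.

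Of 35 genes of cholesterol synthesis and uptake, 6 fell and 29 did not pass; adjusted over the list alone, 16 fell and 1 rose. The 6 included the squalene epoxidase SQLE (-1.09 ± 0.09, adjusted p = 0.0286), the fatty acid desaturase FADS1 (-0.98 ± 0.11, adjusted p = 0.0356) and ACAT2, an acetyl-CoA acetyltransferase (-0.73 ± 0.08, adjusted p = 0.0372). The median was -0.34 (camera, adjusted p = 1.8e-06; adjusted p = 0.26 with an estimated correlation), with -0.13 for siRNA2, which did not pass (adjusted p = 0.234), and -0.52 for siRNA3. Among 59 genes of oxidative phosphorylation, 4 fell, ATP5PB, SDHD, ATP5F1D and NDUFS1, and 55 did not pass; adjusted over the list alone, 10 fell and 1 rose. Their median was -0.23 (camera, adjusted p = 2.33e-04; adjusted p = 0.26 with an estimated correlation). None of 75 ribosomal protein genes passed, over all genes or adjusted over the list alone; their median was -0.17 (camera, adjusted p = 0.00257; adjusted p = 0.37 with an estimated correlation), and without siRNA2 replicate 1 the adjusted p was 0.0881. Among 28 p53 targets, GDF15, a stress-induced cytokine (1.30 ± 0.09, adjusted p = 0.0227), and PMAIP1, which encodes the pro-apoptotic NOXA (0.75 ± 0.09, adjusted p = 0.0395), rose. GDF15 had 2.24 with siRNA2 and 0.36 with siRNA3, which did not pass (limma adjusted p = 0.178). Adjusted over the list alone, 6 p53 targets rose and 1 fell. The median was 0.13 (camera, adjusted p = 4.12e-04; adjusted p = 0.37 with an estimated correlation), with -0.003 for siRNA2 (adjusted p = 0.063) and 0.28 for siRNA3. Among 36 apoptosis regulators, the inflammatory caspase CASP4 rose by 1.27 ± 0.09 (adjusted p = 0.0226); adjusted over the list alone, 10 rose and 2 fell, and the median was 0.21 (camera, adjusted p = 6.3e-04; adjusted p = 0.27 with an estimated correlation). With each array centred on its median in place of loess, the medians of the p53 and apoptosis lists were -0.19 and -0.20, and those of ribosomal proteins and oxidative phosphorylation were -0.96 and -0.80 (siRNA2 -1.21 and -1.03, siRNA3 -0.68 and -0.52). Among genes with mean log2 intensity of at least 10 the ribosomal list did not pass in the mean (adjusted p = 0.0568), with siRNA2 (0.0814) or with siRNA3 (0.118), nor did oxidative phosphorylation with siRNA3 (0.118).

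The other 12 lists did not pass in the mean, with camera adjusted p from 0.0812 to 0.845, and 6 of them held both risen and fallen members. Of 41 genes of invasion and proteolysis, 5 rose and 4 fell, among them the protease inhibitor TIMP1 (1.01 ± 0.09, adjusted p = 0.0286) and the tissue plasminogen activator PLAT (-0.89 ± 0.08, adjusted p = 0.0286), which had 0.29 and 0.41 on the siRNA2 arrays and -2.10 and -2.16 on the siRNA3 arrays. TIMP1 had 1.79 with siRNA2 and 0.23 with siRNA3, which did not pass (limma adjusted p = 0.354). Of 35 histone genes, 4 rose, such as H2BC12 (1.37 ± 0.14, adjusted p = 0.031), and 3 fell, such as H4C2 (-1.46 ± 0.13, adjusted p = 0.0286); adjusted over the list alone, 17 rose and 11 fell. Of 36 epithelial genes, KRT17, CLDN4 and OVOL1 rose, and of 29 mesenchymal and matrix genes the collagen chain COL6A1 rose and COL6A3 fell. Of 39 heat shock and immediate early genes, the transcription factors ATF3 (1.01 ± 0.10, adjusted p = 0.031) and JUNB (1.61 ± 0.19, adjusted p = 0.0374) rose and HSP90AA1 fell. Of 38 genes of the unfolded protein response and ATF4, ATF3 and STC2 rose and DDIT4 fell, and of 36 genes of hypoxia and glycolysis, P4HA2 and ADM rose and GPI fell. Of 14 neuroendocrine genes SCG5 rose, and of 18 leukocyte genes and 28 genes of the RNA interference machinery none passed. The list of 28 androgen-responsive luminal genes had a median of 0.02 (camera, adjusted p = 0.532).

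**Figure D2:**
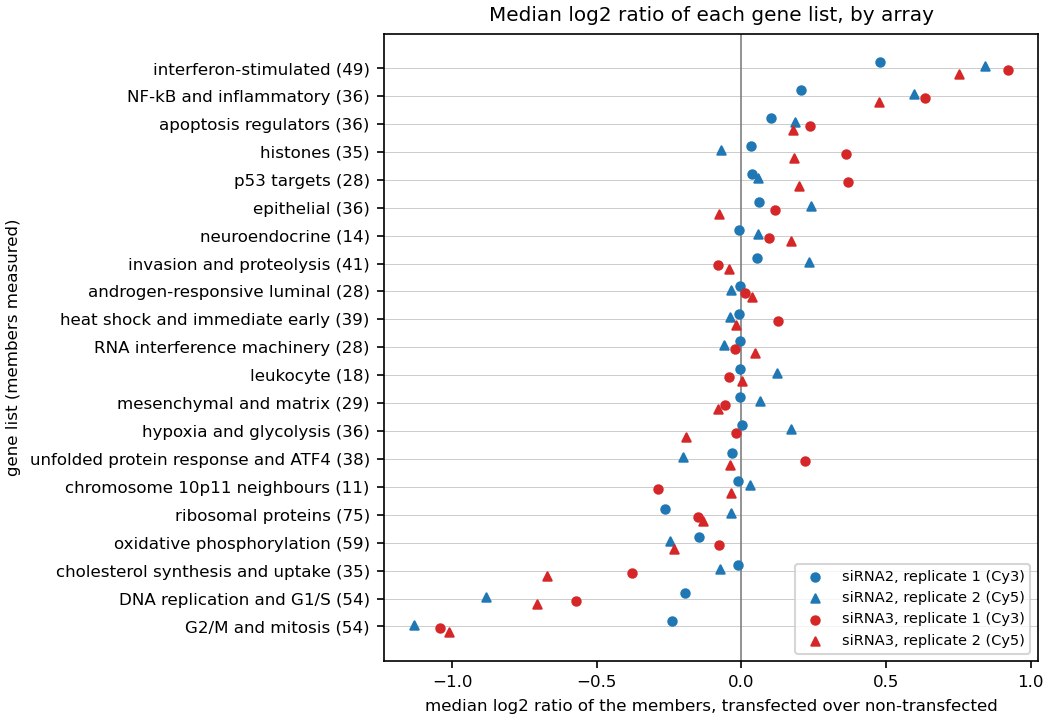
Median log2 ratio of transfected over non-transfected cells (x axis) for each of the 21 gene lists, with the number of measured members in brackets and 1 point per array. The G2/M list lay at -0.24 on siRNA2 replicate 1 and between -1.01 and -1.13 on the other arrays, and the interferon list lay between 0.48 and 0.92.

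A fit without 1 array has fewer residual degrees of freedom, so lost calls do not single out that array, here or with each siRNA. The calls of single genes in this comparison were made with all 4 arrays. Without any 1 of them limma called 0 genes in the mean, with 2872 to 5605 genes at an unadjusted p under 0.05 against 5677 with all arrays, and with median centring in place of loess it called 0, with 587 at an unadjusted p under 0.05. Chance gives 1154 genes at that level, more than the 587, so the test with median centring was conservative. With the siRNA as the replicate limma called 0 genes in the mean, with 3759 at an unadjusted p under 0.05. The balance of directions also moved, to 1940 higher and 2099 lower with no background correction, 2753 and 2616 with Agilent's processed signals and 641 and 751 with the authors' values.

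Genes that passed with siRNA2 included 2 of 49 interferon-stimulated genes, which rose, and 2 of 54 mitotic genes, which fell, in lists that did not pass with an estimated correlation (both adjusted p = 0.34). RSAD2 rose by 3.07 ± 0.12 (SE, n = 2 arrays, limma adjusted p = 0.0381). S100P, a small calcium-binding protein, rose by 3.02 ± 0.19 (adjusted p = 0.0383), an 8.10-fold difference. The secreted protease inhibitors PI3 (elafin) and SLPI rose by 2.39 ± 0.11 and 2.25 ± 0.11 (both adjusted p = 0.0381). BIRC5 fell by 2.20 ± 0.14 (adjusted p = 0.0383).

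In all, 21 genes passed with siRNA2, 17 higher and 4 lower. PLAAT2 (2.97), COXFA4L3 (2.95), the tumour necrosis factor family member LTB (2.26), GDF15 (2.24), IL6 (2.08) and COL6A1 (1.83) completed the 10 largest rises, with adjusted p of 0.0381 or 0.0383. CENPF (-1.98, adjusted p = 0.0395) and the kinetochore protein ZWINT (-1.82, adjusted p = 0.0381) fell. Of 49 interferon-stimulated genes, 2 rose (RSAD2 and BST2) and 47 did not pass; adjusted over the list alone, 24 rose. Their median was 0.79 (camera, adjusted p = 8.21e-24). With an estimated correlation this list and the other 8 that follow for siRNA2 had an adjusted p = 0.34 each. Of 36 NF-kB and inflammatory genes, IL6 rose; adjusted over the list alone, 12 rose, and the median was 0.44 (camera, adjusted p = 2.28e-15). Of 54 G2/M genes, BIRC5 and CENPF fell, and 17 fell when adjusted over the list alone, with a median of -0.77 (camera, adjusted p = 1.32e-26). None of 54 genes of DNA replication passed, and 4 fell when adjusted over the list alone, with a median of -0.55 (camera, adjusted p = 6.48e-19). Medians of oxidative phosphorylation (-0.19, adjusted p = 1.06e-04) and ribosomal protein genes (-0.16, adjusted p = 0.00348) were also negative, with 0 members past the threshold over all genes and 5 and 0 fallen when adjusted over the list alone. Medians of the invasion (0.13, adjusted p = 1.84e-04), epithelial (0.18, adjusted p = 3.34e-04) and apoptosis lists (0.15, adjusted p = 0.00271) were positive, with TIMP1 the only member to pass (1.79 ± 0.13, adjusted p = 0.0466). Adjusted over the list alone, 8, 6 and 2 of their members rose and 2, 1 and 1 fell.

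The siRNA2 arrays differed in the size of the list medians: the G2/M median was -0.24 on replicate 1 and -1.13 on replicate 2, that of DNA replication was -0.19 and -0.88, and that of the interferon list was 0.48 and 0.84. The same held for NF-kB (0.21 and 0.60), epithelial (0.06 and 0.24), invasion (0.06 and 0.23) and ribosomal genes (-0.26 and -0.04), the last with adjusted p = 0.599 without replicate 1. Median centring turned the apoptosis, epithelial and invasion medians to -0.38, -0.35 and -0.22, and left the interferon median at 0.025 (adjusted p = 9.33e-04), in a setting where the median of all genes was -0.22 for siRNA2. The balance of called genes was 905 higher and 933 lower with no background correction and 1522 and 1486 with Agilent's processed signals. With the authors' values and with no filter on dim probes, 0 genes passed with siRNA2. limma called 0 genes for siRNA2 with median centring (225 at an unadjusted p under 0.05) and without any 1 of the arrays (808 to 2985), against 1922 at that level with all arrays.

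With siRNA3, 9 of 36 NF-kB and inflammatory genes and 6 of 49 interferon-stimulated genes rose, and 6 of 54 mitotic genes and 4 of 35 genes of cholesterol synthesis and uptake fell. These lists did not pass with an estimated correlation (adjusted p = 0.36 to 0.42). UBD rose by 4.49 ± 0.44 (SE, n = 2 arrays, limma adjusted p = 0.0492), a 22.5-fold difference, and CCL5 by 2.95 ± 0.30 (adjusted p = 0.0492). HMGB2 fell by 2.61 ± 0.25 (adjusted p = 0.0492). DPYSL2, which binds tubulin, fell by 2.58 ± 0.11 (adjusted p = 0.0439), and PLAT by 2.13 ± 0.11 (adjusted p = 0.0439). DHCR7, the enzyme of the last step of cholesterol synthesis, fell by 1.84 ± 0.15 (adjusted p = 0.0492).

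In all, 174 genes passed with siRNA3, 81 higher and 93 lower. The other largest rises were those of the tight junction gene CLDN14 (2.84), COXFA4L3 (2.54), RSAD2 (2.54), UCA1 (2.49), SOD2 (2.36), the G protein regulator RGS2 (2.35), the collagenase MMP13 (2.32) and the protease inhibitor SPINK6 (2.32), which was well above background in the non-transfected channel on 1 of the 2 arrays. The other largest falls were those of MAP3K20 (-2.58), BIRC5 (-2.22), CCNB1 (-2.10), the HSP90 co-chaperone PTGES3 (-2.09), CENPF (-1.93) and the lysyl oxidase LOXL1 (-1.88). Adjusted p of these genes ran from 0.0439 to 0.0492. With the authors' values 13 genes passed with siRNA3, 13 higher and 0 lower, and 3 of them were among the 174. With no filter on dim probes and with each siRNA fitted alone, 0 passed.

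Of 49 interferon-stimulated genes, 6 rose with siRNA3 and 43 did not pass; adjusted over the list alone, 30 rose. The median was 0.84 (camera, adjusted p = 1.25e-12; adjusted p = 0.36 with an estimated correlation). Of 36 NF-kB and inflammatory genes, 9 rose; adjusted over the list alone, 20 rose and 4 fell. Among them were TRAF1, an adaptor of tumour necrosis factor receptors (2.22, adjusted p = 0.0439), and TNFAIP3, which encodes the NF-kB inhibitor A20 (1.46, adjusted p = 0.0492). The median was 0.57 (camera, adjusted p = 3.54e-07; adjusted p = 0.42 with an estimated correlation). Of 54 G2/M genes, 6 fell, and 50 fell when adjusted over the list alone, with a median of -1.02 (camera, adjusted p = 5.49e-23; adjusted p = 0.42 with an estimated correlation). Of 54 genes of DNA replication, TYMS and UHRF1 fell; adjusted over the list alone, 19 fell and 1 rose, with a median of -0.59 (camera, adjusted p = 1.53e-11; adjusted p = 0.43 with an estimated correlation).

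Of 35 genes of cholesterol synthesis and uptake, 4 fell with siRNA3, among them DHCR7 and ACAT2 (-1.03, adjusted p = 0.0492); adjusted over the list alone, 18 fell. The median was -0.52 (camera, adjusted p = 4.64e-09; adjusted p = 0.36 with an estimated correlation). The p53 list had a median of 0.28 (camera, adjusted p = 3.21e-04; adjusted p = 0.42 with an estimated correlation) with 0 members past the threshold over all genes and 3 risen when adjusted over the list alone. The apoptosis list had 0.16 (adjusted p = 0.00569; adjusted p = 0.36 with an estimated correlation), with CASP4 risen, and 12 risen and 2 fallen when adjusted over the list alone. Oxidative phosphorylation had -0.17 (adjusted p = 0.00896; adjusted p = 0.36 with an estimated correlation), and medians of -0.08 and -0.23 on replicates 1 and 2; 0 members passed, and 3 fell when adjusted over the list alone. Ribosomal protein genes had -0.17 (adjusted p = 0.0309; adjusted p = 0.42 with an estimated correlation), and adjusted p = 0.12 without replicate 1. limma called 0 genes for siRNA3 with median centring (228 at an unadjusted p under 0.05) and without any 1 of the arrays (3669 to 5080), against 5622 at that level with all arrays.

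Both siRNAs were measured against the same kind of control, and 13 genes passed with each of them in the same direction, and none in opposite directions. The 9 that rose were RSAD2, PLAAT2, PLAAT4, COXFA4L3, IL6, BST2, HLA-H, a pseudogene of HLA class I, and the features ENST00000391418 and XR_078642. The 4 that fell were BIRC5, CENPF, ZWINT and the feature NM_181803. BIRC5 fell by 2.20 with siRNA2 and by 2.22 with siRNA3. The count was 0 without any 1 of the arrays, with median centring, with no filter on dim probes, with each siRNA fitted alone and with the authors' values, and 695 with no background correction. Independent lists of these lengths would share 0.06 higher and 0.016 lower genes. The 2 lists were not independent, since both tests used the same variance estimate for each gene. Of the 21 genes called with siRNA2, 20 had the same sign with siRNA3, and of the 174 called with siRNA3, 145 had the same sign with siRNA2. Across all genes the log2 ratios of the siRNAs correlated at r = 0.529. Simulated unchanged groups with a shared control gave 0.5005, a value fixed by letting the control vary as much as each group. The covariance was 0.0668 against a simulated 0.0145, a difference of 0.0524. The same sign was found in 64.6% of genes, against a simulated 66.7%, which was fixed in the same way. The control's real spread was not measured, so the simulation cannot tell how much of the agreement comes from the shared control. The control could not be split, so part of the excess over independent lists may come from the shared control. Part may also come from the shared variance estimate.

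**Figure D3:**
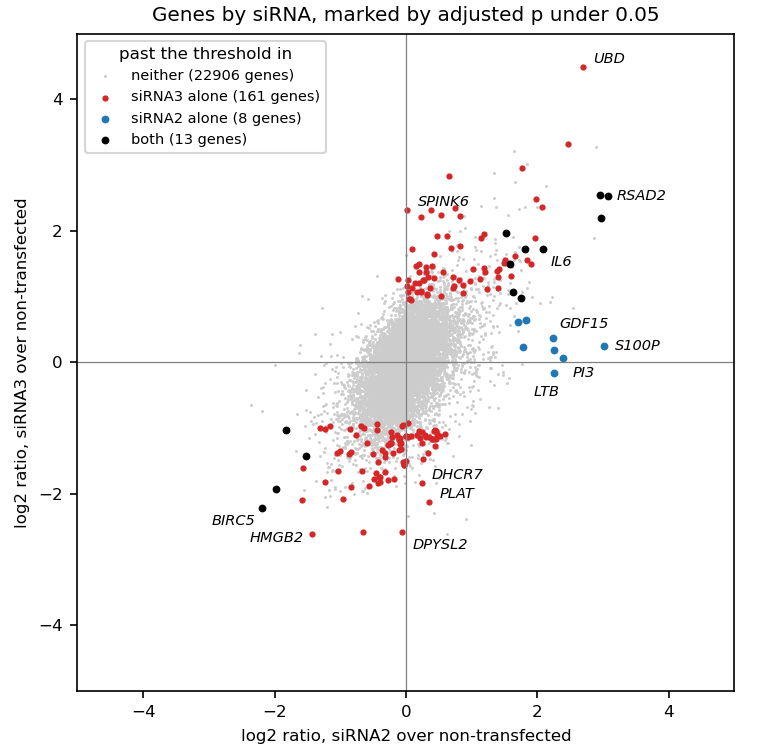
Log2 ratio with siRNA2 (x axis) against log2 ratio with siRNA3 (y axis) for the 23088 genes tested, both over non-transfected cells, with colours for genes past a limma adjusted p of 0.05. The 13 genes past it with both siRNAs lie in the quadrants of equal sign, and PI3 (2.39) and LTB (2.26) lie near 0 on the siRNA3 axis (0.06 and -0.16).

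The last comparison set siRNA2 against siRNA3 directly, as the difference of their log2 ratios. No single gene passed (limma, smallest adjusted p = 0.183), while 2042 genes had an unadjusted p under 0.05, where chance gives 1154. The smallest p-values belonged to DPYSL2, with -0.06 for siRNA2 and -2.58 for siRNA3 (difference 2.52 ± 0.15, adjusted p = 0.183), PLAT, with 0.35 and -2.13 (difference 2.48 ± 0.15, adjusted p = 0.183), and PI3, with 2.39 and 0.06 (difference 2.33 ± 0.15, adjusted p = 0.183). SLPI and LTB followed with differences of 2.06 and 2.42 (both adjusted p = 0.209). In the other direction were SPINK6 (-2.30), well above background on 3 of 4 arrays in the transfected and 2 of 4 in the non-transfected channel, and TRAF1 (-1.99), both with adjusted p = 0.209, the trypsin inhibitor SPINK1 (-1.64, adjusted p = 0.226), the translocon subunit SEC61B (-1.44, adjusted p = 0.266) and TMEM266 (-1.14, adjusted p = 0.274), which was well above background on 3 of 4 arrays in each channel.

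Among the 21 lists, 5 differed between the siRNAs in the camera test, and none of their members passed over all genes. Genes of cholesterol synthesis were higher with siRNA2 than with siRNA3 by a median of 0.51 (adjusted p = 8.67e-09; adjusted p = 0.35 with an estimated correlation), with 5 members higher when adjusted over the list alone. DHCR7 had 0.24 with siRNA2 and -1.84 with siRNA3. The mesenchymal and matrix list was higher with siRNA2 by 0.14 (adjusted p = 1.57e-04; adjusted p = 0.35 with an estimated correlation) and by 0.25 without siRNA3 replicate 1, with 3 members higher when adjusted over the list alone. The invasion and proteolysis list was higher by 0.29 (adjusted p = 3.21e-05; adjusted p = 0.42 with an estimated correlation), with 5 members higher and 1 lower when adjusted over the list alone. Histone genes were lower with siRNA2 by a median of 0.25 (log2 difference -0.25, adjusted p = 7.97e-04; adjusted p = 0.35 with an estimated correlation). With median centring these 4 differences were 0.07, 0.20, 0.07 and -0.77, and among genes with mean log2 intensity of at least 10 they were 0.59, 0.78, 0.60 and -0.29. The G2/M list was higher with siRNA2 by 0.32 (adjusted p = 6.09e-05; adjusted p = 0.70 with an estimated correlation). This last difference rested on siRNA2 replicate 1: without it the value was -0.02 (adjusted p = 0.749), without siRNA2 replicate 2 it was 0.66, and without siRNA3 replicate 1 it was 0.26 (adjusted p = 0.0657). It was -0.15 without background correction, -0.40 with Agilent's processed signals, -0.34 with the authors' values and -0.05 with median centring. The interferon list had a difference of -0.001 (adjusted p = 0.94), which ran from -0.525 with median centring, the only alternative that took it past the threshold, to 0.148 without siRNA2 replicate 1.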

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

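The tests of explanations in this part were chosen after the values were seen. Camera tests of the difference between the siRNAs marked 5 gene lists. The median log2 ratio of siRNA2 minus siRNA3 was 0.323 for G2/M and mitosis, 0.135 for mesenchymal and matrix genes, 0.29 for invasion and proteolysis, 0.513 for cholesterol synthesis and uptake, and -0.247 for histones. With an estimated correlation none of the 5 passed. In data outside the comparisons, the spike-in controls read 2.82 and 2.96 log2 units higher with the siRNA2 RNA than with the non-transfected RNA on siRNA2 replicates 1 and 2.

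With both siRNAs the interferon and inflammatory lists were higher and the cell-cycle lists lower than in non-transfected cells in the camera test, and none of them passed with an estimated correlation. Dye bias would turn the sign of a list between dye orientations, while the smallest of the 4 list medians on any array was 0.193 in the direction of its list. A response to introduced double-stranded RNA or to the reagent may contribute, but the difference of the interferon list between the siRNAs, -0.001, was -0.525 with median centring, loss of the target could give the same values, and no control siRNA was analysed here. The growth state of the non-transfected control cells could also lower the G2/M list with any transfected culture, and the higher of the list's medians was -0.771. These explanations could not be told apart.

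For the lists that differed between the siRNAs, narrow log ratios on siRNA2 replicate 1 were weighed first. Without that array the G2/M difference was -0.023, so that array may account for it. The smallest in size of the other 4 differences was 0.179 without that array, so its narrow ratios alone would not account for them. A difference between RNA preparations could do so: the mean spike-in log2 ratio was 2.66 higher on the siRNA2 arrays than on the siRNA3 arrays, and preparation and siRNA cannot be separated. Different side effects of the siRNA sequences were not tested.

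For the spike-in controls, dye bias would turn the sign between orientations, while the lower of the siRNA2 values was 2.82. Less amplifiable RNA in the siRNA2 labelling reactions could give the mean of 2.89, and a general fall of mRNA per total RNA could as well. Loess would remove such a fall, so the siRNA2 log2 ratios and their differences from siRNA3 do not show changes per total RNA. No yield or cell count was analysed here, and the explanations could not be told apart. No biological explanation was tested for this pattern.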

How the results depend on the processing

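All 88 results of named genes that passed kept their sign in every alternative where they were tested. Much of this was set in advance. The largest rises and falls were named only with the same sign on every array, and several alternatives change the test but not the log2 ratios. Median centring, leaving out any 1 array, each siRNA fitted alone and the siRNA as the replicate left none past the threshold, while 87 or 88 still passed with no background correction, offset 16 or Agilent's signals, 46 with the authors' values and 39 with no filter. The cause was not tested unless stated. Of single-list results, 1452 stayed the same, 42 became stronger, 76 weaker and 14 reversed. Channel signals lay near background (median 67 in the siRNA2 Cy5 channel over 48), which limits the log ratios of dim genes. The slide was not run as a block, since all arrays lay on 1 slide, and the alternatives for the targeted transcript were not run, since no probe was named for it. The difference between the siRNAs stayed at 0 genes in every alternative.

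Counts of genes that passed with limma for siRNA2, siRNA3, the mean and both siRNAs in the same direction were 21, 174, 486 and 13. They were 1838, 1367, 4039 and 695 with no background correction, 47, 762, 844 and 27 with offset 16, 3008, 554, 5369 and 401 with Agilent's processed signals, and 0, 13, 1392 and 0 with the authors' values (4780 genes at an unadjusted p under 0.05 for siRNA2). Median centring gave 0, 0, 0 and 0 (225, 228 and 587 unadjusted, each below the 1154 that chance gives, so the test was conservative there). No filter gave 0, 0, 245 and 0 (2017 and 6440 unadjusted for the siRNAs) over 31879 genes, and well above background in both channels 49, 542, 886 and 29 over 15736. The mean over a gene's probes gave 41, 584 and 27 for siRNA2, siRNA3 and both. It kept 17 of the 21 genes called with siRNA2 and 401 of the 486 called in the mean. Trend and robust prior gave 36, 1242, 1169 and 22. An adjusted p under 0.10 gave 81, 2222, 2472 and 61, and a log2 ratio of at least 1 in size gave 190 in the mean, as looser and stricter thresholds do. The siRNA as the replicate gave 0 in the mean (3759 unadjusted), and each siRNA fitted alone gave 0 and 0 (2039 and 4900) and 0 for both, with fewer residual degrees of freedom. Fits without 1 array also have fewer, so lost calls there do not single out an array. Leaving out 1 array gave 0 to 0 for all 4 counts (unadjusted 808 to 2985, 3669 to 5080 and 2872 to 5605); the lone array of a siRNA was assumed to vary like the others. Among genes with mean log2 intensity of at least 10, an alternative added after the data were examined, 88 passed with siRNA2 and 41 with both. In that setting the epithelial difference passed (0.338, adjusted p = 0.00598), and G2/M did not (0.118, adjusted p = 0.432). The share of higher genes moved too: 905 higher and 933 lower with siRNA2 with no background correction, 1522 and 1486 with Agilent's signals, against 17 and 4; 13 and 0 with siRNA3 and 641 and 751 in the mean with the authors' values, against 81 and 93 and 282 and 204.

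Replicate number equals dye orientation here. With this replicate block (dye term), limma called 0 genes for siRNA2 (3065 at an unadjusted p under 0.05), 806 for siRNA3, 1512 in the mean and 0 for both siRNAs. Deviations of same-numbered arrays correlated at 0.205 over 2 pairs, which share a number and a dye orientation.

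Lists past the threshold were 9, 9, 9 and 5 for siRNA2, siRNA3, the mean and the difference. With an estimated correlation they were 0, 0, 0 and 0, and with fry 0, 2, 3 and 1. The lists that passed fry were interferon, apoptosis and cholesterol in the mean (each adjusted p = 0.042), and cholesterol in the difference (0.029). With siRNA3 they were cholesterol (0.011) and histones (0.03), which camera did not pass. In the mean the NF-kB (0.056), G2/M (0.077) and DNA replication lists (0.095) did not pass fry. The difference had 8 with no background correction, 9 with Agilent's signals, 12 with median centring and 8 with the authors' values; leaving out 1 array gave 4 to 7.

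In the opposite direction, the G2/M difference had adjusted p = 0.00289 with no background correction, 2.39e-07 with Agilent's signals and 1.77e-05 with the authors' values. The DNA replication difference, not past the threshold at first, had 4.33e-07, 2.35e-07 and 7.53e-06, and the NF-kB difference had 0.0336 with Agilent's signals. Leaving out 1 array gave adjusted p from 1.04e-21 to 0.749 for G2/M and from 4.53e-08 to 0.863 for DNA replication. Both were in the opposite direction only without siRNA2 replicate 1 (0.749 and 0.00119), and the lowest values, without siRNA2 replicate 2, were in the original direction. NF-kB had 0.0212 to 0.921. With median centring, siRNA2 apoptosis (adjusted p = 0.273), epithelial (0.24), hypoxia (0.00949) and RNA interference (0.0143) and mean histones (0.0153) turned direction in the camera test. The list median of siRNA2 RNA interference kept its sign, while those of siRNA2 invasion and of mean p53 and apoptosis, among others, changed it. The median of all genes under that setting was -0.221 for siRNA2.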

Other observations

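The 3 lists in this part were written after the values of some of their members were seen, so medians and counts are given with no test of the list. Of 23 measured genes of class I antigen presentation, 1 rose with siRNA2, 5 with siRNA3 and 9 in the mean of both siRNAs, and none fell. The 1 with siRNA2 was the pseudogene HLA-H, also among the 5 and the 9. Its probe was not checked against other HLA genes. Among the 9 were HLA-B (1.53), TAP1 (1.41), a subunit of the peptide transporter, and B2M (1.17), the light chain of class I molecules. The list's median was 0.59 for siRNA2 and 0.584 for siRNA3. Of 14 interferon ligands and receptors, IFNB1 (1.39) and IFNL2 (2.43) rose in the mean, with a list median of 0.38. IFNB1 had 0.53 with siRNA2 (limma adjusted p = 0.661) and 2.24 with siRNA3 (adjusted p = 0.0492). IFNL2 passed with neither siRNA alone (adjusted p = 0.337 and 0.0578).

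Of 22 secreted epithelial defence and S100 genes, PI3, SLPI and S100P rose with siRNA2 and none passed with siRNA3 or in the difference. The list's median was 0.364 with siRNA2 and -0.003 with siRNA3. S100A9, a calcium-binding alarmin, had 0.91 with siRNA2 and -2.38 with siRNA3 (adjusted p of the difference 0.316).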
